A study of Mus musculus with 6 samples.

How the data were processed

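RNA sequencing libraries from 6 samples of the mouse cell line HL-1 were compared, 3 labelled control shRNA and 3 labelled Smyd4 shRNA. Groups and replicate numbers come from the sample titles and the shRNA field of the labels. Per the labels' protocols, RNA was extracted with Trizol and the libraries were prepared with Illumina protocols; whether the preparation kept strand is not given in the sources used here. Per the submitters' processing notes, the tools included TopHat2 2.0.9 and Bowtie2 2.0.6, and the genome build was GRCm38. The read counter, the gene annotation and the authors' statistical test are not given in the sources used here.

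The expression values analysed are FPKM for 22246 Ensembl genes as deposited by the authors, 1 column per library. The authors' deposited comparison table lists 5616 genes with a normalized signal per library, which is the gene's read count divided by 1 size factor per library, together with the authors' gene lengths and coordinates. The log2 fold changes in that table were computed by the authors as labelled Smyd4 shRNA against control. The p-values and adjusted p-values in it are also the authors' own, and the largest adjusted p listed is 0.0499, so the table holds only called genes. For these genes FPKM times gene length divided by the normalized signal is 1 constant, 41.6, with a spread of 1.9e-12. The FPKM values are therefore scaled by the size factors and not by each library's own total, which makes them comparable between libraries as far as those factors are right. A size factor assumes that most genes do not change.

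Because the authors counted whole reads, the number of reads behind each value could be recovered. In every library all values of the comparison table (100%) were whole multiples of 1 step within a tolerance of 1e-04. With a length for each gene, 100% of the FPKM values gave whole reads within 0.01. For genes outside the comparison table that length was itself searched for as one that makes the values whole. Lengths came from the authors for 5616 genes and from the annotation, where it was an exact multiple of the smallest length the values allow, for 13288 genes. For the other 3342 genes the smallest possible length was used, so their read counts are lower bounds. The recovered totals lay between 23414482 and 25267605 reads in the control libraries and between 20755849 and 26387605 in the libraries labelled Smyd4 shRNA. The 10 genes with the most reads took between 4.58% and 4.79% of a library, and mitochondrial genes took between 1.95% and 2.13%. Smyd4, at 12.9 FPKM in the control libraries and a length of 4329 bases, thus rests on 1065 to 1483 reads per library, while genes near 0 FPKM rest on a few reads.

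Gene symbols were assigned by Ensembl identifier, which matched for 22134 of the 22246 genes; 131 symbols differed from the names in the authors' table. Coordinates are on GRCm38, from the authors' table for the genes it lists and from the GENCODE M21 annotation for the others. The annotation is not the one the authors used, since 4228 of the 5616 listed genes had equal coordinates in both. Of the 128 named genes found in that annotation, 36 overlapped another gene of the expression table, and their values may hold reads of the neighbour if counting ignored strand or the neighbour lies on the same strand.

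Values were transformed to log2(FPKM + 0.5), genes with a mean of at least 1 FPKM over the 6 libraries were kept, and groups were compared with limma 3.58.1 (empirical Bayes with a trend) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over all tested genes at a threshold of 0.05. A change on this scale understates the change of genes with low FPKM. Gene lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 29 lists that had at least 3 tested genes, and again with a correlation estimated from the data. Counts of list members were made over all genes tested and adjusted over the list alone. Smyd4 was also tested by an exact two-sided permutation of its 6 values. Levels are given as mean ± SD over 3 libraries where an SD is shown and as means otherwise, and folds between levels are ratios of mean FPKM.

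The groups, the tests, the 32 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Smyd4 first. Among genes past the threshold with non-overlapping groups and a mean of at least 5 FPKM, it took the 12 largest rises and the 12 largest falls, leaving out gene models with only an identifier or a Gm, Rik, AC, AL or pseudogene type name. It then took up to 4 members past the threshold of each list with the smallest adjusted p, up to 2 per direction first, or the 2 members with the highest mean where none passed. Nppa, Myh6 and Gapdh were level checks. Cebpd has the type pseudogene in the authors' table but an ordinary gene name and was kept, a reading of the rule made after its values were seen. Genes outside the rule are said to be chosen after their values were seen. Nppa is not analysed here, and some genes that the rule takes are not reported here.

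Alternatives were a pseudocount of 0.1 or 1, no filter on low values or a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, the replicate number as a block, limma without trend or with robust estimation, leaving out each library in turn, an estimated correlation, the rotation test fry, and the authors' own table. After the data were seen, edgeR 4.0.16 quasi-likelihood tests (TMM or RLE scaling) and DESeq2 1.42.0 on the recovered reads, and removal of each library's trend with GC content, were added. Replicates were compared by chi-square on recovered reads over genes with a summed count of at least 20. The limma pipeline was tested on simulated data made from the means and depths of the 6 libraries, with 11152 genes in its step and 200 genes drawn to change. It recovered 31 of 50 changes at the smallest fold simulated, 98% of changes of 1.5-fold, 100% of changes of 2-fold and 100% of changes of 4-fold. It called 10 unchanged genes and 0 of 100 random lists. Genes were simulated independently of each other, so the random lists held no correlated members. The estimated correlation of the real ribosomal protein list was 0.754, and the 0 of 100 does not gauge false calls in such lists. In the data 3608 of the 5474 called genes changed by less than 1.25-fold, the smallest fold simulated. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.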

Results

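The series compared mRNA levels between cultures of mouse HL-1 cells given a control short hairpin RNA (shRNA) and cultures given an shRNA against Smyd4. HL-1 is an established line derived from mouse atrial cardiomyocytes. An shRNA is a hairpin transcript that is processed into a small interfering RNA and directs degradation of the matching mRNA. Smyd4 encodes a member of the SET and MYND domain family of lysine methyltransferases. Each group held 3 libraries, 6 in all, and the design text of the series states that the comparison was between control cells and cells with lowered Smyd4. The 3 control libraries held 23698856, 23414482 and 25267605 reads assigned to genes, and the 3 libraries labelled Smyd4 shRNA held 26387605, 25170833 and 20755849, as recovered from the deposited values. Genes at 1 FPKM (fragments per kilobase of gene length, scaled for depth) or more numbered 11409, 11400 and 11408 in the control libraries and 11201, 11265 and 11224 in the libraries labelled Smyd4 shRNA. The labels do not state whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

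The targeted gene was examined first. Smyd4 (ENSMUSG00000018809) lies on chromosome 11 from 75348433 to 75405705 of GRCm38 and is protein coding. Its mRNA stood at 12.9 ± 0.539 FPKM (SD, n = 3) in the control libraries and at 12.3 ± 0.348 FPKM (SD, n = 3) in the libraries labelled Smyd4 shRNA. The control libraries held 12.5, 12.8 and 13.5 FPKM and the libraries labelled Smyd4 shRNA 12.6, 12.3 and 11.9 FPKM, so the ranges overlapped. The mean was 5.07% lower, a log2 change of -0.07 with a standard error of 0.04 and a 95% confidence interval from -0.16 to 0.02 (limma, Benjamini-Hochberg adjusted p = 0.173). The lower bound of that interval corresponds to a level 10.7% below control. The exact two-sided permutation test of the 6 values gave p = 0.2, and 0.1 is the smallest p this design allows. Smyd4 had between 1065 and 1483 reads per library. The mRNA level of the target thus goes against the label, and the 3 libraries are called the libraries labelled Smyd4 shRNA from here on. Every direction given below is relative to that label and is not tied to a measured fall of Smyd4 mRNA. Of the other family members, Smyd3 rose from 1.76 ± 0.0278 to 2.38 ± 0.177 FPKM (limma, adjusted p = 0.0043), while Smyd2 stood at 17.3 and 17.5 FPKM and Smyd5 at 8.41 and 7.90 FPKM. Smyd1, the family member known for its role in heart and skeletal muscle, had a mean of 0.0668 FPKM in the control libraries and 0.0255 FPKM in the labelled libraries and was not tested. The list of these 4 genes had 3 tested members, 1 higher and 2 that did not pass (limma camera, adjusted p = 0.781).

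**Figure D1:**
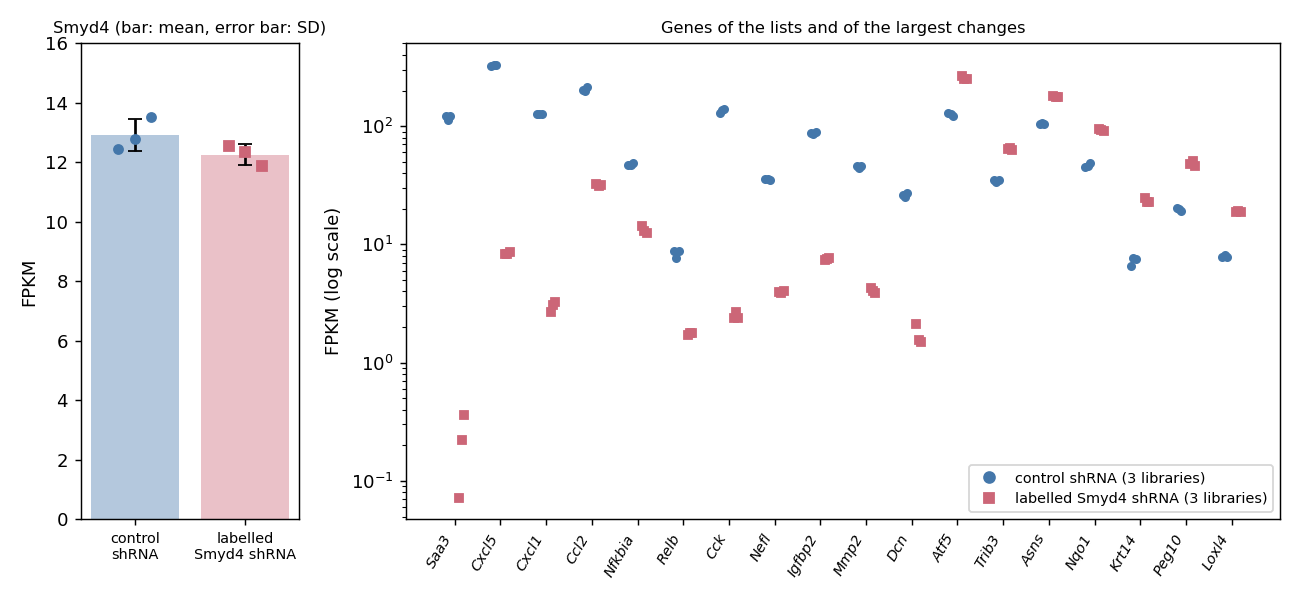
FPKM in each of the 6 libraries: Smyd4 on a linear axis (bars are means and error bars SD of 3 libraries) and 18 other genes on a log axis, with control libraries as circles and libraries labelled Smyd4 shRNA as squares. Smyd4 overlapped between the groups at 12.9 and 12.3 FPKM, whereas Saa3 stood at 119 and 0.220 FPKM and Atf5 at 126 and 256 FPKM; the genes were picked for display after their values were seen.

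Although Smyd4 mRNA differed little, the groups were far apart elsewhere. In the libraries labelled Smyd4 shRNA, 16 of 17 inflammatory genes under NF-kB control, 5 of 5 neuron-associated genes and 5 of 5 skeletal muscle genes with tested values fell. In the same libraries 21 of 23 genes of the integrated stress response and amino acid supply, 29 of 35 ribosomal protein genes and 19 of 28 antioxidant genes rose. These 6 lists passed limma's camera test with a preset correlation. The NF-kB list held with an estimated correlation (adjusted p = 0.0404), and the other 5 did not, with adjusted p from 0.0846 to 0.501 with an estimated correlation. Among genes past the threshold, 254 were at least 2-fold lower and 48 at least 2-fold higher on the log2(FPKM + 0.5) scale. Of 11325 genes tested with limma, 5474 (48.3%) passed a Benjamini-Hochberg adjusted p of 0.05, with 2839 higher and 2635 lower. Which direction held more calls depended on the setting. Lower calls were more with median-of-ratios scaling (2650 higher and 2787 lower), without a filter on low values (2582 higher and 3037 lower) and without replicate 1 of the libraries labelled Smyd4 shRNA (2385 higher and 2410 lower). The median size of a called change was 0.24 on the log2 scale, and 4691 of the called genes changed by less than 1.5-fold. In 57.8% of tested genes the 3 values of one group all lay above the 3 of the other, against 10% by chance.

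Replicates lay close together, with a median SD of 0.06 between replicates on the log2 scale. The edgeR quasi-likelihood test on recovered whole reads, chosen after the data were seen, called 6824 of 13775 genes, 3204 higher and 3620 lower, and 5280 of these were also called by limma. It placed 192 genes at least 2-fold higher and 786 at least 2-fold lower, with more low genes tested and folds of low genes shrunk less than on the log2(FPKM + 0.5) scale. The authors' deposited table lists 5616 genes, 2587 higher and 3029 lower, of which 4678 were also called here and 0 had the opposite sign.

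Saa3, which encodes an acute phase serum amyloid A protein (chromosome 7, 46711998 to 46715676), had the largest fall and dropped from 119 ± 5.20 to 0.220 ± 0.146 FPKM (log2 change -7.40 with a standard error of 0.13; limma, adjusted p = 9.1e-09). Between 1 and 4 reads per library remained, against 1428 to 1655 in the controls. Cck, which encodes the peptide hormone cholecystokinin, was 54.4-fold lower, at 135 ± 6.39 against 2.49 ± 0.149 FPKM. The neutrophil-attracting chemokines Cxcl5 and Cxcl1, which lie close together on chromosome 5, were 38.8-fold and 42.1-fold lower. Cxcl5 stood at 325 ± 4.89 and 8.39 ± 0.231 FPKM and Cxcl1 at 127 ± 0.591 and 3.01 ± 0.292 FPKM. Cebpd, a transcription factor of the acute phase response, fell from 30.4 ± 1.39 to 3.48 ± 0.0674 FPKM. The secreted glycoprotein hormone Stc1 fell from 12.6 to 0.705 FPKM, and Igfbp2, a binding protein of insulin-like growth factors, was 11.6-fold lower (87.1 against 7.52 FPKM). The matrix proteoglycan Dcn was 15.2-fold lower (26.2 against 1.73 FPKM) and the matrix-degrading gelatinase Mmp2 11.2-fold lower (45.3 against 4.05 FPKM). The other large falls were Chrnd, a subunit of the muscle acetylcholine receptor (11.6 to 1.21 FPKM), and the neurofilament genes Nefl (35.3 to 3.99 FPKM) and Nefm (15.6 to 1.87 FPKM). Nefl and Nefm overlap on chromosome 14 on opposite strands, so reads in the shared stretch could not be assigned if counting ignored strand, and Cebpd overlaps Spidr on the opposite strand. All 12 passed in limma with adjusted p between 1.7e-11 and 1.3e-07.

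The largest rises were smaller. Ighv7-1, an immunoglobulin heavy chain variable segment of chromosome 12 (113896408 to 113896946), rose from 0.830 ± 0.238 to 11.1 ± 0.616 FPKM (log2 change 3.14 with a standard error of 0.12; limma, adjusted p = 6.3e-07). It had 5 to 9 reads per control library and 78 to 107 per labelled library. Such segments share sequence with many relatives, so its value is uncertain. Krt14, a keratin of basal epithelial cells, rose 3.24-fold from 7.26 ± 0.585 to 23.5 ± 1.20 FPKM, and Peg10, an imprinted gene derived from a retrotransposon, rose 2.44-fold from 19.8 ± 0.669 to 48.2 ± 2.11 FPKM. Kcnab2, an auxiliary subunit of voltage-gated potassium channels, went from 3.85 to 10.3 FPKM, the matrix protein gene Tinagl1 from 6.59 to 16.6 FPKM and Loxl4, a lysyl oxidase that cross-links collagen, from 7.92 to 18.9 FPKM. Tmem176b rose from 6.91 to 16.9, Glrp1 from 11.5 to 26.4 and the claudin family member Cldn34b1 from 2.69 to 7.39 FPKM. The remaining members of this set were non-coding: the lincRNA D5Ertd605e (3.16 to 8.29 FPKM) and the microRNA locus Mir8091 (2.79 to 7.84 FPKM), which rested on 5 to 28 reads per library. All of these passed in limma, with adjusted p between 6.2e-08 and 0.0047. Kcnab2 and Tmem176b overlap other genes on the opposite strand, and Kcnab2 also overlaps Gm16334 on its own strand. Whether the counting used strand is not given in the sources used here.

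**Figure D2:**
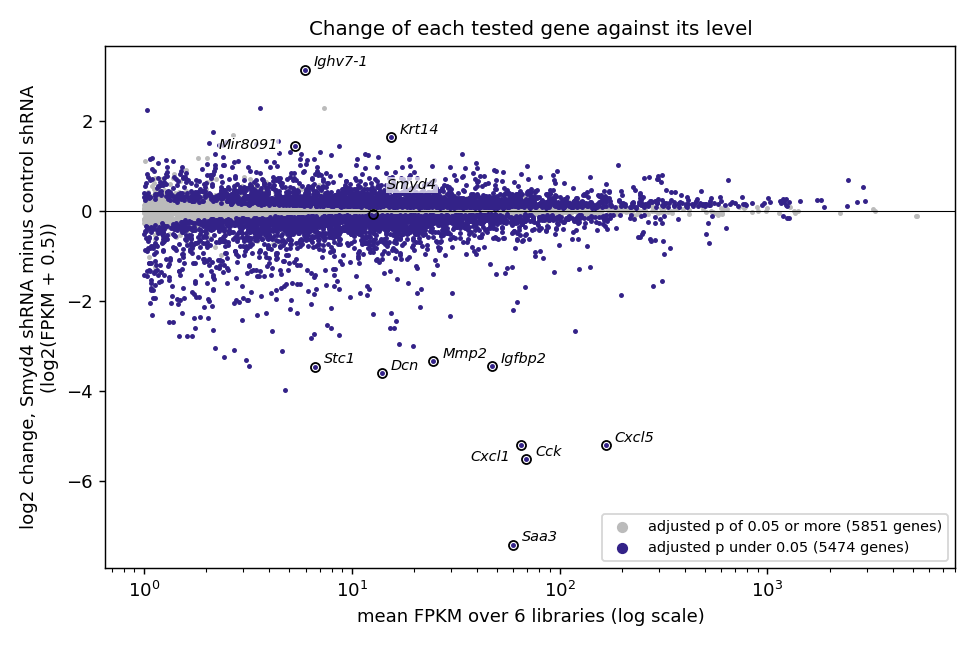
Log2 change of each of the 11325 tested genes (libraries labelled Smyd4 shRNA minus control, on log2(FPKM + 0.5)) against its mean FPKM over the 6 libraries on a log axis, with the 5474 genes past an adjusted p of 0.05 in dark blue. Saa3, Cck, Cxcl5 and Cxcl1 lie lowest, from -7.40 to -5.18, Ighv7-1 highest at 3.14, and Smyd4 at -0.07.

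The gene lists fixed in advance were compared with all other genes by limma's camera test. Of 32 lists, 29 had at least 3 tested members, and 15 passed a Benjamini-Hochberg adjusted p of 0.05 over the lists with a preset correlation of 0.01: 8 were higher and 7 lower in the libraries labelled Smyd4 shRNA. With a correlation estimated from these data, 1 of the 15 calls held and 14 were lost, so each lost call is given with that p as well. Some calls were lost although the estimated correlation lay below the preset 0.01. The neuron list had an estimated correlation of -0.196, and its unadjusted p in limma camera went from 1.5e-07 to 0.0058. Correlation between members therefore does not alone account for the losses. In 27 of the 32 lists the counts of members past the threshold were equal over all genes tested and adjusted over the list alone, and for the other 5 both counts are given.

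Inflammatory genes under NF-kB control fell together. Of 17 tested members, 1 was higher and 16 lower in the libraries labelled Smyd4 shRNA, with a median log2 change of -1.24 (limma camera, adjusted p = 3.6e-12), and this call held with an estimated correlation (adjusted p = 0.0404). Besides Saa3, Cxcl5 and Cxcl1, the monocyte chemoattractant Ccl2 dropped from 205 ± 7.21 to 31.8 ± 0.460 FPKM. The exception was Ptgs2, the inducible cyclooxygenase, which rose from 25.1 to 28.8 FPKM. The immediate early genes, which are induced within minutes of a stimulus, had 3 members higher and 16 lower of 20 tested. Their median log2 change was -0.40 (limma camera, adjusted p = 6.7e-06, and adjusted p = 0.138 with an estimated correlation). Ier3 fell from 79.6 ± 2.71 to 30.1 ± 0.171 FPKM and Junb from 101.3 ± 4.52 to 50.2 ± 1.77 FPKM. The zinc finger factors Egr2 (3.13 to 5.48 FPKM) and Egr3 (3.33 to 5.57 FPKM) rose. Interferon-stimulated genes had 2 members higher, 5 lower and 5 that did not pass of 12 tested, and the list was not called (limma camera, adjusted p = 0.207). It was called lower without a filter on low values (limma camera, adjusted p = 0.0167), and over 19 camera alternatives its p ranged from 0.0167 to 0.396. Among them Isg20 rose from 7.91 to 13.1 FPKM and Isg15 from 1.91 to 2.86 FPKM. The Isg15 call was lost in limma without a filter (adjusted p = 0.0628), without control replicate 1 (0.0514) and without replicate 1 of the libraries labelled Smyd4 shRNA (0.0648). It was also lost in DESeq2 (adjusted p = 0.13, against 0.0183 in limma), and over 18 alternatives its p ranged from 0.00389 to 0.13. In turn Ifit2 fell from 7.76 to 4.85 FPKM and the interferon regulatory factor Irf1 from 9.97 to 7.11 FPKM. The macrophage marker list had 2 tested members, too few for a list test. In it the monocyte surface protein gene Cd14 fell from 27.9 ± 0.846 to 18.6 ± 0.871 FPKM.

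The integrated stress response and amino acid supply genes, targets of the transcription factor Atf4, rose as a group. Of 23 tested members, 21 were higher, 1 was lower and 1 did not pass, with a median log2 change of 0.57 (limma camera, adjusted p = 3.3e-12, and adjusted p = 0.132 with an estimated correlation). The transcription factor Atf5 rose from 126 ± 3.45 to 256 ± 6.63 FPKM, the pseudokinase Trib3 from 34.6 ± 0.914 to 64.1 ± 1.08 FPKM and the asparagine synthetase gene Asns from 105 ± 0.596 to 177 ± 2.46 FPKM. Atf3, which belongs to the same response and is also an immediate early gene, fell from 7.02 ± 0.333 to 4.28 ± 0.145 FPKM. The endoplasmic reticulum stress list, which shares Trib3 and Asns, had 15 members higher, 6 lower and 8 that did not pass of 29 tested. Adjusted over the list alone, 15 were higher and 7 lower (limma camera, adjusted p = 0.0369, and adjusted p = 0.422 with an estimated correlation). Its falls included the phosphatase subunit gene Ppp1r15a (7.21 to 5.21 FPKM) and the disulfide isomerase gene Pdia4 (67.8 to 56.1 FPKM). Ribosomal protein genes moved by small and even amounts, with 29 higher, 0 lower and 6 that did not pass of 35 tested. The median log2 change was 0.15 (limma camera, adjusted p = 1.2e-05, and adjusted p = 0.501 with an estimated correlation). Rpl14 rose from 676 ± 25.3 to 834 ± 27.6 FPKM and Rpl15 from 177 ± 5.86 to 210 ± 5.63 FPKM. Ribosomal protein genes have many processed pseudogenes, which makes the single values less certain.

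Genes of antioxidant defence controlled by Nrf2 rose, with 19 higher, 3 lower and 6 that did not pass of 28 tested. Adjusted over the list alone, 19 were higher and 4 lower (limma camera, adjusted p = 0.000368, and adjusted p = 0.233 with an estimated correlation). The quinone reductase gene Nqo1 rose from 46.3 ± 1.90 to 92.6 ± 1.38 FPKM, and G6pdx, the entry enzyme of the pentose phosphate pathway, rose from 47.9 ± 0.613 to 63.8 ± 0.504 FPKM. The glutathione transferase gene Gsta2 fell from 3.40 to 0.909 FPKM and the exporter gene Abcc1 from 10.6 to 9.49 FPKM; Gsta2 has close paralogs, so its value is uncertain. Cholesterol synthesis genes had 15 members higher, 4 lower and 5 that did not pass of 24 (limma camera, adjusted p = 0.00663, and adjusted p = 0.138 with an estimated correlation). Lss, the lanosterol synthase gene, rose from 7.36 ± 0.311 to 10.5 ± 0.0962 FPKM and Dhcr7, which acts at the last step, from 9.19 to 12.3 FPKM. The regulator Srebf2 fell from 98.4 to 88.2 FPKM and the sterol carrier gene Stard4 from 15.1 to 13.3 FPKM. The fatty acid and lipid synthesis list had 9 members higher and 2 lower of 16, and 11 higher and 2 lower adjusted over the list alone (limma camera, adjusted p = 0.0337, and adjusted p = 0.215 with an estimated correlation). The desaturase genes Fads2 (114 to 148 FPKM) and Fads1 (54.8 to 71.1 FPKM) rose, and the cholesterol exporter gene Abca1 (2.05 to 1.14 FPKM) and Mylip, which targets the LDL receptor for degradation (7.02 to 6.04 FPKM), fell. The Mylip call (limma, adjusted p = 0.0195) was lost without a filter (0.0508), after quantile normalization (0.0512), without control replicate 2 (0.0530) and without control replicate 3 (0.0570). It was also lost without replicate 2 (limma, adjusted p = 0.0507) or replicate 3 (0.0565) of the libraries labelled Smyd4 shRNA and in DESeq2 (0.0572), and over 19 alternatives its p ranged from 0.00566 to 0.0572. Heat shock and chaperone genes had 13 members higher, 4 lower and 3 that did not pass of 20 (limma camera, adjusted p = 0.0369, and adjusted p = 0.50 with an estimated correlation). The mitochondrial chaperonin gene Hspd1 rose from 284 to 338 FPKM and Hspa4 from 88.3 to 102 FPKM. The small heat shock protein genes Hspb1 (463 ± 19.2 to 156 ± 7.73 FPKM) and Hspb8 (38.4 to 30.2 FPKM) fell. After quantile normalization the calls of the endoplasmic reticulum stress (adjusted p = 0.119), lipid synthesis (0.0946) and heat shock (0.181) lists were lost, in limma's camera test. Over 19 camera alternatives p ranged from 0.00339 to 0.422 for the first and from 0.00478 to 0.215 for the second. The heat shock call was also lost with a mean FPKM of at least 5 (adjusted p = 0.0873), without control replicate 2 (0.0667) and without replicate 3 of the libraries labelled Smyd4 shRNA (0.0715) in limma camera, and over 19 camera alternatives its p ranged from 0.00497 to 0.50.

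Cell cycle genes were slightly higher. Of 36 tested members, 18 were higher, 3 lower and 15 did not pass, with a median log2 change of 0.08 (limma camera, adjusted p = 0.0075, and adjusted p = 0.396 with an estimated correlation). The replication licensing genes Mcm5 (54.0 ± 2.11 to 69.9 ± 0.255 FPKM) and Mcm3 (63.2 to 74.5 FPKM) rose, and the mitotic kinesin gene Kif20a (45.6 to 37.6 FPKM) and the centromere histone gene Cenpa (28.0 to 24.6 FPKM) fell. This call was lost after quantile normalization (limma camera, adjusted p = 0.0592), and over 19 camera alternatives its p ranged from 0.000139 to 0.396. The p53 target list went the other way, with 3 higher, 13 lower and 6 that did not pass of 22. Adjusted over the list alone, 4 were higher and 13 lower (limma camera, adjusted p = 0.00118, and adjusted p = 0.143 with an estimated correlation). Pmaip1, which encodes the pro-apoptotic protein Noxa, fell from 3.48 ± 0.205 to 0.419 ± 0.108 FPKM and the kinase gene Plk2 from 28.4 ± 0.585 to 9.04 ± 0.501 FPKM. Sesn2 (18.4 to 23.1 FPKM) and Gdf15 (12.3 to 14.6 FPKM), both also induced in the integrated stress response, rose. Of the histone genes, 3 of 4 tested members were higher and 1 did not pass, and the list was not called (limma camera, adjusted p = 0.0521). It was called higher without a filter (limma camera, adjusted p = 0.0477), with median-of-ratios scaling (0.0419), without control replicate 2 (0.0384) and without replicate 2 (0.0393) or replicate 3 (0.0473) of the libraries labelled Smyd4 shRNA. Over 18 camera alternatives its p ranged from 0.0384 to 0.227. Hist1h1c rose from 19.3 to 29.3 FPKM, Hist1h2bc from 12.7 to 19.1 FPKM and Hist1h1b from 0.944 to 1.46 FPKM. The Hist1h1b call (limma, adjusted p = 0.0217) was lost without a filter (0.0597), without control replicate 3 (0.0670) and without replicate 2 of the libraries labelled Smyd4 shRNA (0.0675). It was also lost in edgeR (adjusted p = 0.0676 with TMM and 0.0651 with RLE) and DESeq2 (0.27), and over 18 alternatives its p ranged from 0.00946 to 0.27. Histone genes occur in near-identical copies, so these values are uncertain. The list of histone methyltransferases, demethylases and deacetylases had 4 members higher, 13 lower and 18 that did not pass of 35 and was not called (adjusted p = 0.165, limma camera). In it Nsd1 fell from 4.21 to 2.85 FPKM and Kdm1a from 18.4 to 14.9 FPKM, and Hdac4 rose from 3.14 to 3.93 FPKM and Dot1l from 8.63 to 9.90 FPKM.

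**Figure D3:**
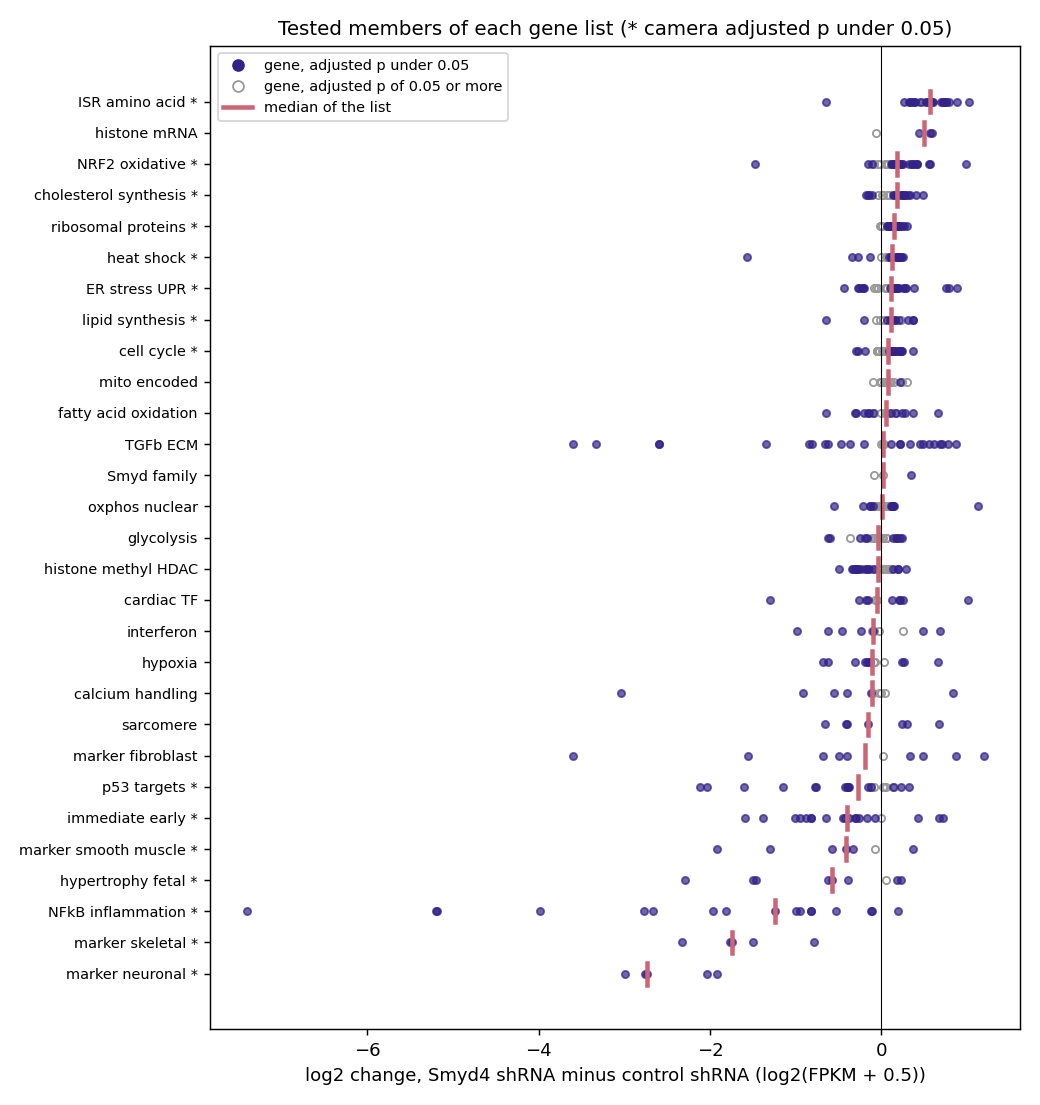
Log2 change of every tested member of the 29 tested lists (libraries labelled Smyd4 shRNA minus control, on log2(FPKM + 0.5)), with filled points for genes past an adjusted p of 0.05, open points for the others and a bar at the list's median. Lists are ordered by their median, from -2.73 for neuronal markers to 0.57 for the integrated stress response, and an asterisk marks the 15 lists past an adjusted p of 0.05 in camera with the preset correlation.

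Regulators and receptor genes of the skeletal muscle lineage were present in these cells and fell in the libraries labelled Smyd4 shRNA, whereas most genes of the cardiac sarcomere list lay under 1 FPKM. All 5 tested members of the skeletal muscle marker list fell, while the other 10 of the 15 measured stayed under 1 FPKM in all 6 libraries (median log2 -1.74; limma camera, adjusted p = 2.0e-05, and adjusted p = 0.122 with an estimated correlation). The acetylcholine receptor subunit gene Chrna1 fell from 49.9 ± 0.828 to 9.59 ± 0.298 FPKM, the fast-fibre actinin gene Actn3 from 9.81 ± 0.265 to 2.54 ± 0.195 FPKM. The myogenic regulators fell as well, Myod1 from 18.8 ± 0.831 to 5.31 ± 0.707 FPKM and Myf5 from 8.68 ± 0.305 to 4.83 ± 0.0678 FPKM. Of 27 measured genes of the cardiac sarcomere list, 20 stayed under 1 FPKM in all 6 libraries and 7 were tested, of which 3 were higher and 4 lower (limma camera, adjusted p = 0.633). Myh6, the atrial and adult ventricular myosin heavy chain of the mouse, had a mean of 0.00207 FPKM in the control libraries and 0.0127 FPKM in the labelled libraries. The cardiac troponin T gene Tnnt2 rose from 7.11 ± 0.264 to 11.7 ± 0.398 FPKM and the tropomyosin gene Tpm1 from 82.1 to 96.8 FPKM. The intermediate filament gene Des fell from 137 ± 1.26 to 102 ± 1.21 FPKM and the small chaperone gene Cryab from 118 to 89.4 FPKM. Nppa is not analysed here. The cardiac transcription factor list had 5 members higher, 4 lower and 2 that did not pass of 11, was not called (limma camera, adjusted p = 0.845), and had a median and a mean log2 change below 0 although the test pointed up. Nkx2-5, a regulator of heart development, rose from 3.57 ± 0.659 to 7.68 ± 0.607 FPKM and Srf from 21.0 to 24.5 FPKM, and Irx3 (5.14 to 1.79 FPKM) and Tbx3 (2.34 to 1.87 FPKM) fell. The Tbx3 call was lost after quantile normalization (limma, adjusted p = 0.0516), and over 19 alternatives its p ranged from 0.000433 to 0.0516. Calcium handling and ion channel genes had 1 member higher, 5 lower and 4 that did not pass of 10 tested (limma camera, adjusted p = 0.0617). The list was called without replicate 2 of the libraries labelled Smyd4 shRNA (limma camera, adjusted p = 0.0393), and over 19 camera alternatives its p ranged from 0.0393 to 0.23. The inward rectifier channel gene Kcnj2 dropped from 4.32 ± 0.131 to 0.0877 ± 0.0320 FPKM and the junctophilin gene Jph2 from 14.5 to 9.79 FPKM. The potassium channel gene Kcnh2 rose from 1.01 to 2.18 FPKM. The hypertrophy and fetal gene list had 2 members higher, 6 lower and 1 that did not pass of 9 (limma camera, adjusted p = 0.013, and adjusted p = 0.143 with an estimated correlation). In it the LIM domain gene Fhl1 fell from 21.3 ± 0.223 to 3.95 ± 0.0937 FPKM and the mechanically induced gene Ankrd1 from 149 to 97.1 FPKM, and Fhl2 rose from 27.6 to 31.5 FPKM.

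**Figure D4:**
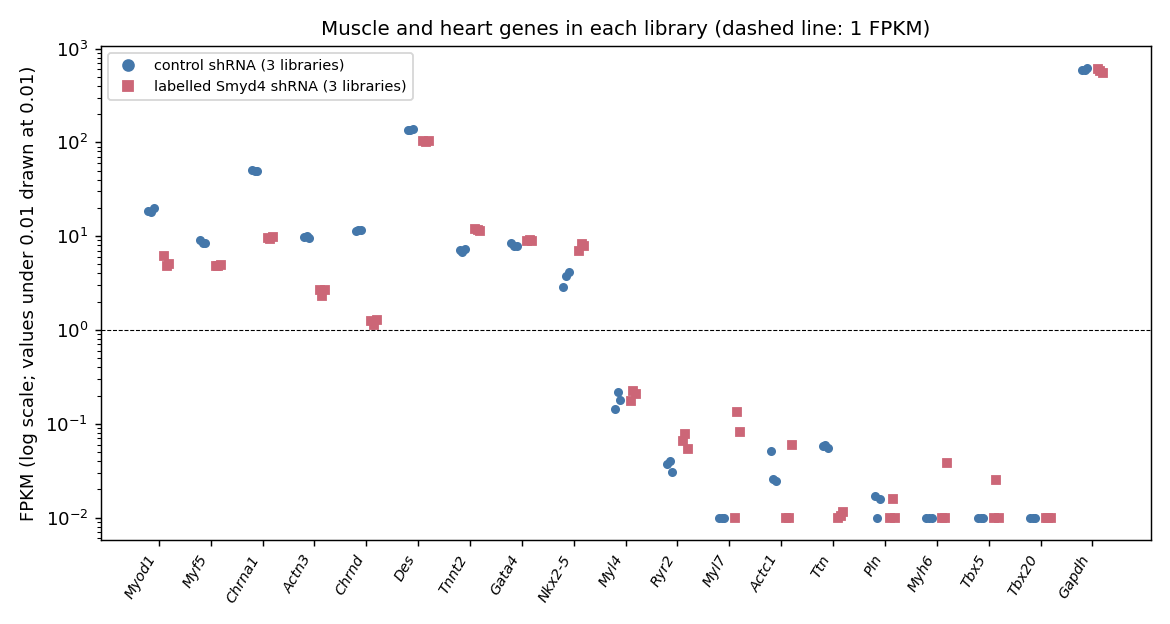
FPKM of muscle and heart genes and of Gapdh in each of the 6 libraries on a log axis, with control libraries as circles, libraries labelled Smyd4 shRNA as squares and a dashed line at 1 FPKM. Myod1, Chrna1 and Des lie above the line in every library and Myl4, Ryr2, Ttn and Myh6 below it; the genes were picked for display after their values were seen.

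Among markers of other cell types, neuron-associated genes showed the lowest list median. All 5 tested members fell, of 9 measured (median log2 -2.73; limma camera, adjusted p = 1.4e-06, and adjusted p = 0.0846 with an estimated correlation). Besides Nefl and Nefm, the growth cone gene Gap43 fell from 11.8 ± 0.639 to 1.35 ± 0.170 FPKM and the tubulin gene Tubb3 from 100.1 ± 3.99 to 24.1 ± 1.01 FPKM. Smooth muscle markers had 1 member higher, 5 lower and 1 that did not pass of 7 (limma camera, adjusted p = 0.00527, and adjusted p = 0.143 with an estimated correlation). Tagln fell from 15.8 ± 0.731 to 3.82 ± 0.287 FPKM and Acta2, which is also in the hypertrophy list, from 292 ± 6.33 to 196 ± 4.32 FPKM, while the kinase gene Mylk rose from 1.09 to 1.56 FPKM. Fibroblast markers split, with 4 higher, 5 lower and 1 that did not pass of 10 (limma camera, adjusted p = 0.781). Next to the fall of Dcn, the microfibril gene Mfap5 fell from 2.86 to 0.648 FPKM, but the collagen genes Col1a1 (37.6 ± 1.06 to 69.3 ± 3.66 FPKM) and Col1a2 (60.5 to 84.9 FPKM) rose. The extracellular matrix list divided in the same way, with 12 higher, 12 lower and 3 that did not pass of 27 (limma camera, adjusted p = 0.633), a median log2 change of 0.02 and a mean of -0.42. The basement membrane collagen genes Col4a1 (31.7 ± 0.838 to 54.6 ± 1.04 FPKM) and Col4a2 (29.6 to 48.5 FPKM) rose, and the proteoglycan gene Bgn fell from 26.5 ± 0.594 to 3.96 ± 0.0673 FPKM, as Mmp2 did. The endothelial and epithelial marker lists had 1 tested member each, too few for a list test. Flt1, a receptor of vascular endothelial growth factor, rose from 0.473 to 1.66 FPKM and the keratin gene Krt19 from 53.3 ± 1.07 to 87.1 ± 1.78 FPKM.

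No list of energy metabolism was called by limma's camera test. The rotation test fry called the glycolysis list (fry, adjusted p = 0.0434) and the hypoxia list (fry, adjusted p = 0.00627) lower. Nuclear genes of oxidative phosphorylation had 7 members higher, 5 lower and 20 that did not pass of 32 (limma camera, adjusted p = 0.765). The 14 tested mitochondrially encoded genes had 1 higher, 0 lower and 13 that did not pass (limma camera, adjusted p = 0.513). The direction of both lists flips after quantile normalization. Cox6a2, the heart and skeletal muscle isoform of a cytochrome oxidase subunit, rose from 3.64 ± 0.237 to 8.52 ± 0.182 FPKM and Sdhc from 29.7 to 32.8 FPKM. In contrast Cycs (57.6 to 49.5 FPKM) and Cox6c (60.1 to 54.6 FPKM) fell. The Cox6c call was lost without control replicate 2 (limma, adjusted p = 0.0518), and over 20 alternatives its p ranged from 0.000298 to 0.0518. The mitochondrial ribosomal RNA mt-Rnr2 rose from 146 to 170 FPKM. Fatty acid oxidation had 6 members higher, 7 lower and 9 that did not pass of 22 (limma camera, adjusted p = 0.781). Pdk4, a kinase that restrains glucose oxidation, rose from 8.38 to 13.6 FPKM and Hadh from 17.1 to 20.3 FPKM. The nuclear receptor gene Esrra (20.1 to 12.7 FPKM) and the dehydrogenase gene Acadm (37.6 to 30.5 FPKM) fell. Glycolysis had 5 members higher, 5 lower and 12 that did not pass of 22 (limma camera, adjusted p = 0.61). The glucose transporter gene Slc2a1 fell from 61.5 ± 1.26 to 39.9 ± 0.754 FPKM and the hexokinase gene Hk2 from 20.8 to 13.5 FPKM. Pkm rose from 1656 to 1957 FPKM and Pfkm from 34.0 to 39.5 FPKM, and Gapdh stood at 595 ± 16.6 and 576 ± 23.7 FPKM. After quantile normalization the log2 change of Pkm shrank from 0.24 to 0.05 and its call was lost (limma, adjusted p = 0.0915), and over 20 alternatives its p ranged from 4.7e-21 to 0.0915. Hypoxia-responsive genes had 3 members higher, 7 lower and 4 that did not pass of 14, and 3 higher and 8 lower adjusted over the list alone (limma camera, adjusted p = 0.165). Bnip3, a mitophagy gene, fell from 31.9 to 19.7 FPKM, whereas the oxidoreductase gene Ero1l rose from 31.3 to 49.7 FPKM and Vegfa from 59.7 to 70.4 FPKM.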

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

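The tests on recovered reads (edgeR and DESeq2) and the removal of the GC trend were chosen after the data were seen; the other alternatives were planned. The number of called genes stayed within 1.5 times of 5474 under every alternative run: from 4573 to 4997 when 1 library was left out, 5619 without a filter (of 22246 genes), 4337 at a mean of at least 5 FPKM, 5437 with median-of-ratios scaling and 5628 after quantile normalization. It was 5926 after removal of the GC trend, 6824 and 6871 with edgeR (TMM and RLE) and 5569 with DESeq2. Calls were 3585 higher and 2341 lower after removal of the GC trend and 3163 higher and 2465 lower after quantile normalization. Lower calls were more with edgeR RLE (3324 higher and 3547 lower) and DESeq2 (2557 higher and 3012 lower), and the cause was not tested. The log2 change of Smyd4 lay between -0.097 and -0.040 and never passed. Counts of large changes depended on the scale and the filter by construction. Genes at least 2-fold higher numbered 31 with a pseudocount of 1, 23 at a mean of at least 5 FPKM, 192 with edgeR under either scaling, 195 with DESeq2 and 73 in the authors' deposited table, against 48. Genes at least 2-fold lower numbered 99 at a mean of at least 5 FPKM, 786 with edgeR TMM, 787 with edgeR RLE, 855 with DESeq2 and 497 in the authors' deposited table, against 254. Of the 15 called lists, 1 held with an estimated correlation, and 23 lists passed in fry. That test asks whether a list's genes move on balance and not whether they differ from other genes. Fry alone, against camera with the preset correlation, called calcium handling, interferon, extracellular matrix, fibroblast markers, glycolysis and hypoxia lower. It also called histone methyltransferases, demethylases and deacetylases lower and histone genes higher.

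With the replicate number as a replicate block, limma called 5141 genes, 4978 of them shared with 5474, and 14 lists, the heat shock list being lost (adjusted p = 0.0532). The numbers do not pair the libraries: deviations of libraries with the same number correlated at -0.032, 0.018 and 0.0069. The block changed no other list call. Camera's direction turned in 5 lists, none of which passed in either setting, and the cause was not tested. These were fatty acid oxidation without a filter (adjusted p = 0.994) and at a mean of at least 5 FPKM (0.938), fibroblast markers at a mean of at least 5 FPKM (0.579), oxidative phosphorylation and mitochondrially encoded genes after quantile normalization (0.679 and 0.728), and cardiac transcription factors on recovered reads (0.964 with TMM and 0.960 with RLE). When 1 library was left out, the adjusted p ranged from 0.271 to 0.987 for oxidative phosphorylation, which turned without control replicate 1 (0.890), and from 0.164 to 0.834 for mitochondrially encoded genes, which turned without replicate 3 of the libraries labelled Smyd4 shRNA (0.834). Of the named genes, 0 changed direction in any alternative, and 20 of their values over all alternatives no longer passed. In the simulated data changes of 1.5-fold were recovered in 98% of genes, and 31 of 50 at the smallest fold simulated.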

Other observations

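Gene groups outside the fixed lists, put together after the changes of some of their members were seen, add further detail and are not independent evidence of direction. Genes of the muscle acetylcholine receptor and its clustering had 1 member higher and 5 lower of 7 tested in the libraries labelled Smyd4 shRNA (limma camera, adjusted p = 0.0026 over 6 such groups, and adjusted p = 0.136 with an estimated correlation). Besides Chrna1 and Chrnd, the subunit gene Chrnb1 fell from 10.7 to 5.52 FPKM and the clustering protein gene Rapsn from 13.7 to 8.55 FPKM, while the nerve-derived organizer Agrn rose from 5.08 to 5.72 FPKM. The 2 metallothionein genes with tested values, too few for a list test, fell, Mt1 from 331 to 216 FPKM (limma, adjusted p = 1.4e-05) and Mt2 from 309 to 84.3 FPKM (limma, adjusted p = 4.3e-08).

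Integrins divided, with 7 genes higher and 3 lower of 11 tested, and the group was not called (limma camera, adjusted p = 0.107). Itga6, a subunit of laminin receptors, rose to 39.6 FPKM, a log2 change of 0.97, and Itgb7 from 23.8 to 46.6 FPKM, whereas Itga7, the laminin receptor subunit of muscle, fell from 79.1 to 32.8 FPKM. Imprinted genes had 1 member higher, Peg10, and 5 lower of 8 tested (limma camera, adjusted p = 0.0926), with Peg3 at 7.25 and 2.64 FPKM and the non-coding RNA H19 at 18.7 and 9.85 FPKM. Binding proteins of insulin-like growth factors had 2 higher and 3 lower of 6 (limma camera, adjusted p = 0.15), with Igfbp3 at 2.57 and 0.0605 FPKM next to Igfbp6 at 227 and 393 FPKM. The C/EBP family had 1 higher and 3 lower of 5 (limma camera, adjusted p = 0.164). Notch pathway genes had 5 higher and 4 lower of 9 (limma camera, adjusted p = 0.984), with the receptor genes Notch1 (3.02 to 1.70 FPKM), Notch2 (18.2 to 14.5 FPKM) and Notch3 (20.8 to 16.1 FPKM) falling.

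In the paragraphs that follow, the tests of Smyd4 across settings, of swapped libraries and of the level of cardiomyocyte genes were chosen after the values they concern were seen.

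Smyd4 mRNA was close in both groups although 5474 other genes passed the test. A fall hidden by the choice among the settings run is argued against by the lowest log2 change over all of them, -0.097. Every scaling used assumes that most genes do not change, so these settings could not show a fall hidden by a shift of most genes. A swap between the groups is argued against by the correlation of each library with its own group, which exceeded that with the other group by at least 0.0216. Reads of an overlapping gene could not hold the value up in the annotation used, where 0 genes overlap Smyd4. It stays open whether the shRNA acted on the protein without lowering the mRNA, whether the fall had been lost by the time of harvest, or whether the label of the whole group is wrong, and none of these was tested. The differences between the groups may therefore come from something other than less Smyd4 mRNA.

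The labels name a cardiomyocyte line, but myogenic genes were present and cardiomyocyte genes near 0. A small share of skeletal muscle cells among cardiomyocytes is argued against by the highest level of Myh6, Myl7, Myl4, Actc1, Ryr2, Pln and Ttn in any library, 0.222 FPKM. For Myod1, Chrna1, Cdh15, Actn3, Chrnd, Des and Tnnt2 the authors' own names differed in 0 cases, which argues against a wrong pairing of these symbols. The near-0 cardiomyocyte genes were not part of that check. Marker lists were also written before the values of their genes were looked at. Of the markers found in the expression table, 11 of 19 for skeletal myoblasts (57.9%) and 2 of 17 for cardiomyocytes (11.8%) reached 1 FPKM in all 6 libraries. The former include Itga7 and Sgca, which heart also expresses. Each list was written with 22 markers, and counting the absent ones as under 1 FPKM would lower both shares. Among the markers found the difference was 46.1 percentage points (Fisher's exact test across genes, two-sided p = 0.0058, with genes not independent). These values are consistent with the hypothesis that the sequenced cells were closer to skeletal myoblasts than to cardiomyocytes, but some of the myoblast markers belong to the acetylcholine receptor group, of which Chrna1 and Chrnd had been seen, and are not independent of these. Cells that lost cardiac genes in culture remain possible, and Nkx2-5 and Gata4 at several FPKM go with that reading. Of the 20 measured members of the cardiac transcription factor list, 8 stayed under 1 FPKM in all 6 libraries. Of the 15 measured skeletal muscle markers, 10 did, so these lists do not decide between the readings. Loss of cardiac genes alone would not account for Myod1 at 18.8 and Myf5 at 8.68 FPKM in the control libraries. No test separated the 2 readings.

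Among the tested genes 48.3% passed. Of the 10 ways to split the 6 libraries into groups of 3, 1 gave as many called genes, the real one with 5474, and the highest other gave 0, and for the gene lists 1 of 10 splits gave as many, the real one with 15, and the highest other gave 8. The splits are too few for a share under 0.05 in either case. Every other split also mixes libraries of both groups, so the group difference widens the spread within its sides. The 0 called genes in those splits is therefore no measure of chance. A GC trend as the whole cause is argued against by 5926 called genes after its removal. Across genes the log2 change had a Spearman correlation of 0.0484 with GC content and -0.126 with gene length, and the length trend was not removed. Repeated sequencing of 1 library per group is argued against by the smallest chi-square per degree of freedom within a group, 1.642, where counting error alone gives about 1. The labels name 0 batches, so a culture, infection or library batch that follows the groups cannot be told apart from the shRNA and could account for part of the changes.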
